A study of Arabidopsis thaliana with 8 samples.

How the data were processed

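The series holds 8 single-colour Affymetrix arrays of Arabidopsis thaliana, 1 per sample, in 4 groups of 2: seedlings with estradiol, seedlings with mock treatment, protoplasts with 35S:ORE1 and protoplasts labelled WT. The labels do not say whether the replicates are separate plants, cultures or preparations, so p-values may measure technical spread. For the WT protoplasts, the time of harvest and whether they were mock-transfected are not given in the sources used here.

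The deposited values are log2 expression values per probe set. The submitters' processing notes name GCRMA and RMA, without versions and without saying which was used for which arrays. Both protoplast arrays of a number share 1 lowest value (2.19 for number 1 and 2.18 for number 2), and 13500 and 11130 probe sets respectively have exactly equal values on them, 4453 and 3048 of these above the lowest value. The 4 seedling arrays have no common lowest value, with minima of 3.25 to 3.35, and share 20 and 8 equal values per number. From these values, each protoplast pair appears to have been processed by itself. The replicate number may therefore stand for a processing batch in protoplasts. The main fit has no block, and blocked values and values within pairs are given beside the results. In seedlings the equal values give no such sign, though same-numbered arrays deviated together there too. The SEs given are from the fit without a block, and the blocked fit leaves 2 residual degrees of freedom. Deviations of same-numbered arrays from their group means correlated at 0.656 in seedlings and 0.787 in protoplasts, over 2 pairs each.

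Gene names came from the table of probe genes supplied with the platform, updated through locus tags of the reference gene table. Of 22810 probe sets, 64 are controls, 13513 have 1 gene symbol, 503 have several and 8730 others are not listed. Of those with 1 symbol, 13436 matched a locus tag, giving 13355 distinct genes, and for the 147 genes with several probe sets the one with the highest mean represents the gene. A probe set with several genes or none is given by its ID. ORE1 has no listed probe set, so its own change, although planned as a check of the labels, was not analysed here.

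Probe sets that were not controls and reached log2 5 on at least 2 of the 8 arrays were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). All 4 groups entered 1 model with group means and no block, which leaves 4 residual degrees of freedom, and the prior added 2.25. Both contrasts thus share the same SE for a probe set, so steady or floored protoplast values can narrow a seedling SE. Contrasts were estradiol minus mock, 35S:ORE1 minus WT, and the former minus the latter. An exact permutation test of 2 against 2 cannot give a two-sided p under 0.333, so none was used. A protoplast value within 0.1 of the lowest value of its array counts as being at that value, and a rise from a group with both arrays there is given as a lower bound, the difference of the means. Such a bound holds on the deposited scale only, as another scaling or background correction can give a smaller change.

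The lists of genes were fixed before the data were examined, as were the tests and the rule for named genes. Of 408 genes in 29 lists, 71 have a listed probe set. Whether the arrays measure the others is not known, as 8730 probe sets are not listed. Counts of list members below refer to tested genes with a listed probe set. Lists with at least 3 tested genes (11 lists) were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, and adjusted over the lists. Camera compares a list with the other genes. In protoplasts the median change of all tested probe sets was 0, and many values were exactly equal within a pair. A small shift of expressed genes can therefore be called there. The lists for jasmonate, salicylic acid, senescence NAC factors, miR164 targets, nitrogen remobilisation, epidermis, vasculature and reference genes had no tested member. Those for chlorophyll breakdown, nucleases, ethylene, abscisic acid, chlorophyll synthesis, auxin, cytokinin, the clock, guard and myrosin cells and root hairs had 1 or 2 and no set test. Of the members of these, 1 passed over all probe sets, ARR16 in protoplasts. A further 28 families were grouped by gene symbol after the probe table, but before any comparison, had been seen.

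The rule named, per comparison, up to 15 rises and 8 falls with the largest log2 fold change among genes past the threshold whose arrays did not overlap between the groups. A comparison with under 10 such genes was filled to 10 by the largest moderated t. It further named up to 15 genes past the threshold in both systems, up to 10 with the largest difference between systems, all measured reported ORE1 targets and up to 4 members of every other list per comparison. Probe sets and families outside it were chosen after their values were seen.

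Overlap was compared with the count for independent lists. The seedling shift of the probe sets that changed in protoplasts was tested with camera and against 10000 random lists matched on seedling level, a test chosen after the counts were seen. On simulated data with 17388 probe sets, limma recovered 33.2% of 2-fold and 75.5% of 4-fold changes for the seedling contrast, with 3.93% false calls. For the protoplast contrast it recovered 36.4% and 75.3%, with 5.22% false calls. The simulated noise was independent between arrays and equally wide on all of them, with no floor and no equal values. These rates therefore need not hold for the real arrays. Alternatives were other filters, quantile normalization, median centring, a spread prior with trend, array weights, the replicate block, only the 4 arrays of a comparison, leaving out each array, other thresholds and 1 probe set per gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No array was left out.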

Results

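Transcript levels of Arabidopsis thaliana were measured on 8 Affymetrix arrays, 2 in each of 4 groups, to compare groups in which ORE1 was to be raised with their controls. ORE1 is a NAC transcription factor known to promote leaf senescence. The seedling system used 2-week-old whole seedlings of a line in which estradiol induces ORE1, kept for 2 h with 10 µM estradiol or with 0.1% ethanol as mock treatment. The protoplast system used mesophyll cell protoplasts from 5-week-old Col-0 plants, either 6 h into transient expression of a 35S:ORE1 construct or labelled wild type (WT), with no time given for the latter. Of 22746 probe sets that were not controls, 17388 reached log2 5 on at least 2 arrays and were tested. Median values were 6.71 to 6.79 on the seedling arrays and 3.35 to 3.54 on the protoplast arrays, where 39.8% to 41.6% of the probe sets lay within 0.1 of the array's lowest value. The systems therefore lie on differently processed scales, and only changes within a system were compared. With 2 arrays per group, their number limits the precision. ORE1 itself has no probe set in the table of probe names and was not analysed here.

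The seedling comparison set estradiol against mock treatment in the inducible line. After 2 h of estradiol, 1 probe set passed the threshold, 262454_at, which the probe table does not list with a gene. It rose from a mean log2 value of 5.26 to 7.29, a change of 2.03 ± 0.12 (SE, n = 2 arrays per group; limma adjusted p = 0.0287). None fell past the threshold in limma. With the replicate number as a block the adjusted p of 262454_at was 0.129, and neither that fit nor one with a trend in the spread called any probe set. After quantile normalization 7 probe sets were called higher and 2 lower. At an unadjusted p under 0.05 there were 343 higher and 375 lower probe sets, 718 in all, where chance alone gives 869.4.

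Markers of developmental cell death lay higher in the estradiol arrays. Of the 15 members of the list, 4 have a listed probe set. All 4 had a higher mean, none passed the test over all probe sets, and 3 passed when adjusted over the list alone. Those 3 were DMP4, which encodes a membrane protein of senescing and dying cells (1.54 ± 0.26, SE, log2), the serine carboxypeptidase-like gene SCPL48 (1.11 ± 0.18) and EXI1 (0.63 ± 0.22), while PASPA3, an aspartic protease gene, changed by 0.11 ± 0.25. The list as a whole shifted upward against the other genes (camera adjusted p = 2.09e-05 over 11 lists, median 0.87, or 0.58 after quantile normalization). With an estimated correlation its adjusted p was 0.0926. For DMP4 the SDs were 0.51 with estradiol and 0.31 with mock, against 0.08 and 0.01 in protoplasts with 35S:ORE1 and WT. Its seedling SE, and its pass over the list alone, therefore rest partly on the steadier protoplast arrays. In a fit to the 4 seedling arrays alone no probe set passed.

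Reported ORE1 targets also shifted upward in seedlings (median 1.81, or 2.80 after quantile normalization, camera adjusted p = 0.00243; adjusted p = 0.200 with an estimated correlation). Of the 10 members of the list, 3 have a listed probe set. None of the 3 passed over all probe sets and 2 passed when adjusted over the list alone. The sugar exporter gene SWEET15, also called SAG29, was higher by 2.08 ± 0.63 and SINA1 by 1.81 ± 0.42, and NOL, which encodes a chlorophyll b reductase, by 0.16 ± 0.22. Some of these genes became known as ORE1 targets from arrays of this kind, so the list is not independent evidence of its direction.

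Of the 10 named genes with the largest moderated t in seedlings, none passed the threshold (limma adjusted p 0.213 to 0.475). The largest of these changes were those of ChiC, a chitinase gene, at 1.62 ± 0.24, AT1G80450 at 1.44 ± 0.23, AT1G74010 (2.65-fold) and AT3G04000, which encodes an aldehyde reductase, at 1.35 ± 0.15. AT2G16900 (1.24), AT1G63840 (1.07), AT1G75900 (1.02), AT1G60750 (0.86) and AT4G27660 (0.86) were higher, and the dehydrin gene LTI30 was lower (-0.83). No member of the lists for senescence-associated genes, autophagy, photosynthesis, vacuolar proteases, heat shock, unfolded protein response, detoxification or expansins passed over all probe sets, and no camera call was made for them (adjusted p 0.385 to 0.806). The 3 touch and early stress genes, CML38, ZAT10 and CML37, were lower by a median of -0.21 (camera adjusted p = 0.0561). The call on 262454_at was lost when any 1 of the 8 arrays was left out. The shift of the reported targets was lost without estradiol replicate 2 and without mock replicate 1, whereas that of the cell death markers was called without each array in turn. A downward shift was called for expansins without estradiol replicate 1 and without mock replicate 2, and for the touch genes without mock replicate 1.

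**Figure D1:**
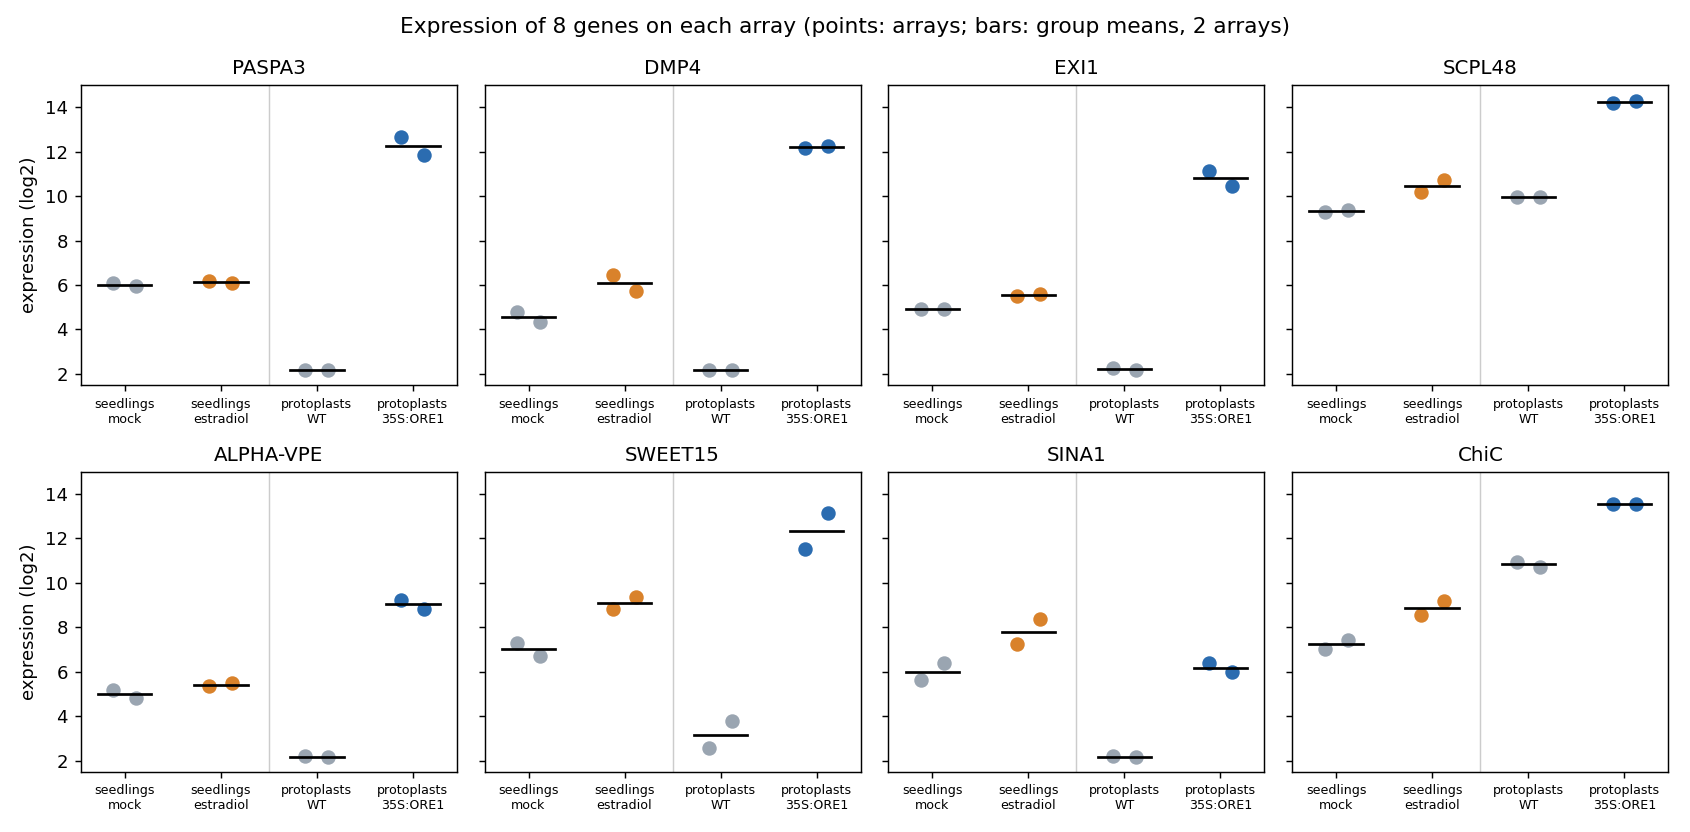
Log2 expression of PASPA3, DMP4, EXI1, SCPL48, ALPHA-VPE, SWEET15, SINA1 and ChiC on each of the 8 arrays, with a point per array and a bar at the mean of the 2 arrays of each group. In protoplasts both 35S:ORE1 arrays lie above both WT arrays for all 8 genes. In protoplasts PASPA3 lies near the lowest value in WT and averages 12.26 with 35S:ORE1.

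The protoplast comparison was included to see the response to ORE1 without estradiol. Here 522 probe sets rose and 134 fell, 656 of 17388 (limma adjusted p under 0.05, n = 2 arrays per group). Of these, 276 of the rises and 67 of the falls belong to a probe set with 1 listed gene. The rises were large: 452 were at least 2-fold and 125 at least 10-fold, against 80 falls of at least 2-fold. For 84 of the risen probe sets both WT arrays lay within 0.1 of the lowest value of their array, so that their change is a lower bound on the deposited scale.

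The 4 markers of developmental cell death with a listed probe set, of 15 in the list, all rose in protoplasts. Their median was 9.29 on the log2 scale when genes at the lowest value in WT are taken at their bound, and 7.51 after quantile normalization. PASPA3 rose by at least 10.08 ± 0.25 (SE, limma adjusted p = 1.04e-05), at least 1080-fold on the deposited scale. DMP4 rose by at least 10.01 ± 0.26 and EXI1 by at least 8.56 ± 0.22, each with the same adjusted p, and SCPL48 by 4.29 ± 0.18, from a mean of 9.96 to 14.25. The list shifted upward (camera adjusted p = 2.57e-18; adjusted p = 0.00871 with an estimated correlation). Among vacuolar and senescence proteases, 3 of 6 rose, namely PASPA3, SCPL48 and ALPHA-VPE, a vacuolar processing enzyme gene (at least 6.85 ± 0.19, adjusted p = 1.14e-05). GAMMA-VPE (0.02), BETA-VPE (-0.37) and the cathepsin B gene CATHB3 (0.34) did not pass. The protease list shifted upward (camera adjusted p = 2.51e-07; adjusted p = 0.0436 with an estimated correlation). It shares PASPA3 and SCPL48 with the cell death markers, so its shift is not independent of theirs.

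Of the 3 reported ORE1 targets with a listed probe set, from 10 in the list, 2 rose over all probe sets and 3 when adjusted over the list alone. SWEET15 rose by 9.15 ± 0.63 (adjusted p = 0.000648), from 3.17 to 12.32, and SINA1 by at least 4.00 ± 0.42 (adjusted p = 0.00423). NOL was higher by 0.55 ± 0.22 (adjusted p = 0.371, and 0.0357 with the replicate number as a block). The list shifted upward (camera adjusted p = 2.51e-06; adjusted p = 0.0436 with an estimated correlation), and as in seedlings it is not independent evidence. SWEET15 was the 1 of 5 measured senescence-associated genes, from 25 in the list, that rose. SAG101 (-0.60), WRKY22 (0.15) and WRKY6 (-0.06) did not pass, and WRKY53 lay at the lowest value in both groups.

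Of 11 autophagy genes none passed over all probe sets, 4 passed when adjusted over the list alone, and 9 had a higher mean, with a median of 0.40, or 0.22 after median centring. The largest were ATG8C at 1.15 ± 0.24 (adjusted p = 0.0638) and ATG4B at 0.99 ± 0.23 (adjusted p = 0.0956), which passed with the replicate number as a block (adjusted p = 0.0224 and 0.00912). ATG8C also passed under 5 other alternatives (adjusted p = 0.0230 to 0.0469). The camera call (adjusted p = 0.000289) was not made with an estimated correlation (adjusted p = 0.278). ATG8F (-0.09) and ATG8G (-0.24) were lower. Of 5 measured photosynthesis genes, from 32 in the list, none passed. LHCB4.2 (-0.61), PSAN (-0.45), RCA (-0.42) and LHCB4.1 (-0.33) had lower means and LHCB4.3 lay at the lowest value in both groups. The list's camera adjusted p was 0.179, 0.596 with an estimated correlation, and 0.0353 with the replicate number as a block. In the cytokinin list, 1 of 2 measured genes rose, the response regulator gene ARR16, by 4.87 ± 0.33 (adjusted p = 0.000653).

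The named rule gave 15 rises of 6.09 or more on the log2 scale in protoplasts, 12 of them lower bounds (adjusted p 2.73e-06 to 0.00115). Besides the genes above these were AT1G24430 (at least 8.15), AT2G44260 (at least 7.53), AT1G20180 (7.35), AT1G17310 (at least 128-fold), AT5G16230 (at least 6.97), the peroxidase gene AT5G66390 (6.85), AT4G34320 (at least 6.76), the purple acid phosphatase gene PAP20 (at least 6.50), AT5G08480 (at least 6.22) and AT3G10590 (at least 6.09). The 8 largest falls were smaller (adjusted p 0.00220 to 0.0200). They were those of the beta-glucosidase gene BGLU27 (-2.32), AT1G72920 (-2.17), AT3G46110 (-2.06), the flavin monooxygenase gene FMO (-1.85), AT1G22890 (-1.78), AT2G39980 (-1.64), AT2G23270 (-1.63) and AT2G29340 (-1.56). With the replicate number as a block, AT1G72920 no longer passed (adjusted p = 0.0562). In a fit to the 4 protoplast arrays alone none of the 8 falls passed (adjusted p 0.0582 to 0.202), nor did SWEET15, AT5G66390, AT5G08480 and ARR16 (0.0618 to 0.115), and after quantile normalization AT1G72920, AT2G23270 and AT2G29340 did not (0.0566 to 0.169).

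Heat shock, unfolded protein response, touch and early stress, detoxification and expansin genes gave no camera call in protoplasts (adjusted p 0.260 to 0.930), and none of their members passed. Of the markers of other cells, FAMA and GC1 of guard and myrosin cells and EXPA7 and EXPA18 of root hairs lay near the lowest value on all protoplast arrays, so no change could be measured there. In seedlings none of these 4 passed over all probe sets, and GC1 (-0.40 ± 0.13) passed as lower when adjusted over its list alone.

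The same-numbered protoplast arrays share a lowest value and 13500 and 11130 exactly equal values, so the replicate number may stand for a processing batch there. The counts above come from the fit without a block. With the replicate number as a block, 1343 probe sets passed, 820 higher and 523 lower (61.1% higher), including 614 of the 656. Within both pairs 521 were at least 2-fold higher and 106 at least 2-fold lower. The share of rises, 79.6%, thus depended on the block, on scaling and on the arrays fitted. After centring each array on its median, which moved the protoplast changes by -0.17, 473 were higher and 326 lower (59.2%). After quantile normalization 359 were higher and 38 lower (90.4%). A fit to the 4 protoplast arrays alone called 135 higher and 10 lower (93.1%). Without WT replicate 1 the count was 407, and without WT replicate 2 it was 376.

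**Figure D2:**
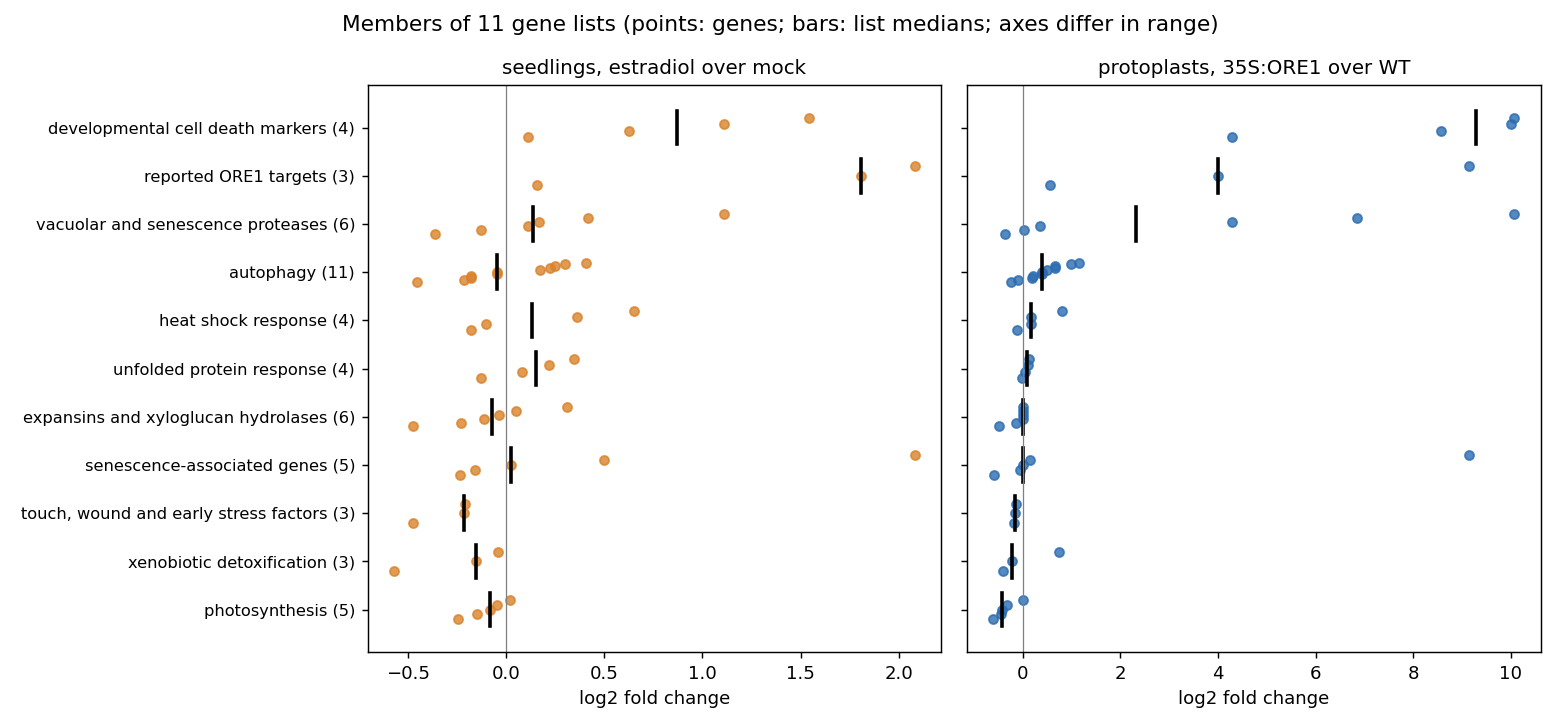
Log2 fold change of each measured member of 11 gene lists in seedlings (estradiol over mock, left) and protoplasts (35S:ORE1 over WT, right), with a point per gene and a bar at the list's median. The ranges of the axes differ. Cell death markers have the highest median in protoplasts, 9.29 (7.51 after quantile normalization), and one of 0.87 in seedlings.

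The change itself differed between the systems for 281 probe sets (limma, seedling change minus protoplast change). For 254 the change was more positive in protoplasts, and 251 of these also rose there. The 10 named genes with the largest difference were PASPA3 (-9.96 ± 0.35, SE, adjusted p = 0.000117), DMP4 (-8.47 ± 0.37), AT1G24430 (-8.12), EXI1 (-7.94), SWEET15 (-7.07 ± 0.88, adjusted p = 0.0175), AT1G17310 (-6.81), AT1G20180 (-6.79), AT5G16230 (-6.78), AT2G44260 (-6.66) and ALPHA-VPE (-6.43). For the other 27 the change was more positive in seedlings, and 21 of these fell in protoplasts, while none rose in seedlings by the test. This count of 27 depended on the setting, with 105 when the replicate number was a block and 12 after quantile normalization. Tissue, time, way of raising ORE1 and processing of the arrays all differ between the systems. The call on SWEET15 was lost without each seedling array in turn (-6.77 to -7.36, adjusted p = 0.116 to 0.140) and after quantile normalization, which also reduced the difference itself (-3.93, adjusted p = 0.0864). Where both WT arrays lay near the lowest value, the protoplast change in the difference is a bound on the deposited scale only. The systems lie on differently processed scales, so the size of the difference itself is not bounded. With the replicate number as a block 487 probe sets passed, without WT replicate 1 it was 184, and without 1 of the seedling arrays 130 to 153.

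Both systems were then set side by side for genes that moved the same way. By adjusted p, 1 probe set rose in both, 262454_at (at least 10.03 ± 0.12 in protoplasts), where independent lists give 0.0300, and none did with the block, with a trend or without any 1 of the arrays. By the rule of at least 2-fold in both same-numbered pairs, which carries no test per gene, 31 probe sets were higher in seedlings and 521 in protoplasts, and 12 were in both. Independent lists give 0.929 (one-sided Fisher's exact test over probe sets, which are not independent replicates, p = 3.88e-11). None was lower in both, where 0.0427 are given by chance. Those 12, singled out after their values were seen, include SWEET15, DMP4, SINA1, ChiC, AT5G39520, AT1G73750, AT1G80450, AT1G74010, AT2G47950 and AT2G31945, of which the last 2 did not pass the test in protoplasts (adjusted p = 0.119 and 0.0860, and 0.0291 and 0.0102 with the replicate number as a block). The other two were 262454_at and 249467_at, which the probe table does not list. ORE1 has no listed probe set either, so an unlisted probe set that is higher in both systems can be that of ORE1 itself rather than of a responding gene. For 249467_at the change was 3.65 ± 0.45 in seedlings (adjusted p = 0.263) and 3.26 ± 0.45 in protoplasts (adjusted p = 0.0128).

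The 522 probe sets that rose in protoplasts were shifted upward in seedlings, by a median of 0.11 against 0.02 for all probe sets. Of them 375, or 71.8%, had a higher mean with estradiol, against 54.1% of all. The shift was 0.11 in replicate pair 1 and 0.12 in pair 2 (camera p = 1.11e-06, p = 0.00151 with an estimated correlation, and p = 0.000101 with the replicate number as a block). The 134 that fell in protoplasts had a seedling median of -0.07, with -0.025 in pair 1 and -0.072 in pair 2, and 55 of them, 41.0%, were higher (camera p = 0.00259, p = 0.0101 with an estimated correlation, and p = 0.0192 with the block, or p = 0.0875 with both).

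**Figure D3:**
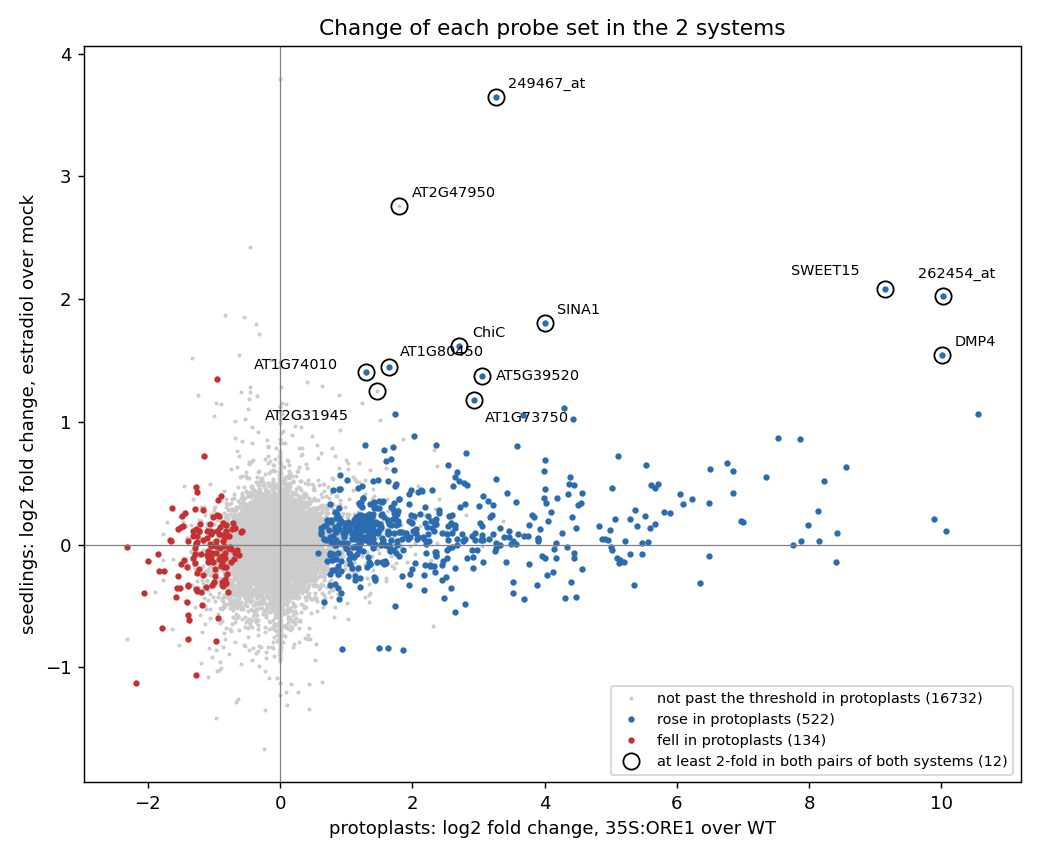
Log2 fold change of 17388 probe sets in protoplasts (horizontal, 35S:ORE1 over WT) and seedlings (vertical, estradiol over mock), with a point per probe set. Blue points are the 522 that rose and red points the 134 that fell in protoplasts, and circles mark the 12 that were at least 2-fold higher in both replicate pairs of both systems.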

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

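The patterns below were picked after the counts were seen, and the bounds of their tests were set before the test values were computed, except that the gap between replicate pairs was examined only after the SDs had been seen. The test of the difference between the systems itself was planned.

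The seedling change, estradiol over mock, and the protoplast change, 35S:ORE1 over WT, differed for 281 probe sets (limma test of the difference, adjusted p under 0.05). Effects of transfection and culture time in protoplasts are not separated from those of ORE1. For the 10 named genes the change in seedlings minus that in protoplasts, on the log2 scale, was -9.96 for PASPA3, -8.47 for DMP4, -8.12 for AT1G24430, -7.94 for EXI1, -7.07 for SWEET15, -6.81 for AT1G17310, -6.79 for AT1G20180, -6.78 for AT5G16230, -6.66 for AT2G44260 and -6.43 for ALPHA-VPE. The call on SWEET15 was lost after quantile normalization (-3.93, adjusted p = 0.0864) and without each seedling array (-6.77 to -7.36, adjusted p = 0.116 to 0.140), over a range of 0.00472 to 0.140 for all alternatives. The protoplast means with 35S:ORE1 were 9.04 for ALPHA-VPE, 12.26 for PASPA3 and 12.20 for DMP4, from WT groups with both arrays near the lowest value. Levels below that value are not measured, so the sizes and order of the differences hold for the deposited values only.

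Many more probe sets changed in protoplasts, 656, than in seedlings, 1. A small spread of floored and tied protoplast values is argued against as the whole cause. The check took 5520 probe sets with a mean of at least log2 8 over the 8 arrays and used no spread. Of these, 190 in protoplasts and 25 in seedlings were 2-fold changed in both replicate pairs, a ratio of 7.60. A probe set near the lowest value in WT can still reach that mean, so folds raised by the floor are not excluded. A wider spread between the seedling replicates could not weaken the seedling test alone, since both contrasts use the same SE for a probe set. The comparison of SDs therefore cannot decide between the counts of that test. Over the same probe sets the median SD was 0.151 in seedlings and 0.188 in protoplasts, a ratio of 0.804, so the seedling spread was not the wider. The median gap between the changes of the 2 pairs, which a shift common to a pair leaves alone, was 0.142 and 0.156. Folds widened by the background correction of the protoplast arrays stay open, since at a mean of at least log2 10 the ratio was 3 (36 and 12 of 1743 probe sets). A longer time (6 h against 2 h), a higher amount of ORE1 and a different tissue may each contribute. So may the handling of the WT protoplasts, whose time and transfection are not given. The design confounds them and they were not tested.

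Rises outnumber falls in protoplasts, 522 to 134. A floor that hides falls is argued against as the whole cause: among the 264 calls with a protoplast mean of at least log2 8 there were 194 rises and 70 falls, or 73.5% rises (95% interval 67.9 to 78.4, counting error only). The scaling of the protoplast arrays stays open. Centring on bright probe sets gave 548 rises and 144 falls (79.2%) but moved the median change by only 0.0074, too little to test it, while the share was 59.2% with arrays centred on their median (a shift of -0.17), 61.1% with the replicate number as a block and 90.4% after quantile normalization. Activation of transcription by ORE1 is a candidate explanation too and was not tested.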

How the results depend on the processing

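Alternatives added after the data were seen were the fit to 4 arrays with their own filter, centring on bright probe sets, the unadjusted p and an adjusted p under 0.1; all others were planned. Of 114 alternatives of the counts, 65 lay within 1.5 times of the value reported. The seedling count of 1 was 9 by quantile normalization, 0 with trend, with trend and robust, with the replicate number as a block, on 4 arrays (also with their own filter), with 1 probe set per gene and without each array in turn (0 to 0), 718 at an unadjusted p under 0.05 and 38 by 2-fold pairs. The protoplast count of 656 was 397 by quantile normalization, 1343 with the block, 145 on 4 arrays, 431 with their own filter, 338 per gene and 376 to 528 leaving out an array; the per-gene fit tests fewer probe sets and the fit to 4 arrays has fewer degrees of freedom. The difference count of 281 was 487 with the block, 146 per gene and 130 to 250 leaving out an array. The shared count of 1 was 2 by quantile normalization, 12 by 2-fold pairs and 0 with trend, with trend and robust, with the block, on 4 arrays, per gene and without each array in turn (0 to 0). Of the lists, 2 in seedlings were 0 with an estimated correlation, 1 by fry and 1 to 3 leaving out an array, and 4 in protoplasts stayed within 1.5 times. With 1 array of a group left out, the lone one is assumed to vary like the other groups.

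Of 147 named gene results under 2997 alternatives, 2881 kept direction and side of the threshold, 33 lost the threshold, 8 crossed it and 75 turned sign. Filters, spread priors, the block and leaving out arrays of the other system do not alter a gene's fold change. Its direction could not turn under these. Of the 147 results, 111 did not pass to begin with. The 2881 were thus partly fixed in advance and are no measure of robustness. No result past the threshold turned sign. Of the named gene results, 16 changed side. On the 4 protoplast arrays alone 12 calls were lost, those of SWEET15 (adjusted p = 0.107), AT5G66390 (0.115), AT5G08480 (0.0618), ARR16 (0.0951) and the 8 falls (0.0582 to 0.202). The call on AT1G72920 was lost under 8 alternatives, among them the block (adjusted p = 0.0562), and those on AT3G46110, AT2G23270 and AT2G29340 without some single arrays (0.0528 to 0.0733). Quantile normalization also ended those on AT2G23270 (0.169) and AT2G29340 (0.0566). The call on the SWEET15 difference was lost by quantile normalization (adjusted p = 0.0864) and without each seedling array (adjusted p = 0.116 to 0.140). Calls were gained for ATG8C under 6 alternatives (adjusted p = 0.0224 to 0.0469) and, with the block, for NOL (0.0357) and ATG4B (0.00912). Among uncalled genes, ranges over the arrays left out (log2) were in seedlings NOL -0.11 to 0.42, SGRL -1.23 to 0.28, WRKY22 -0.14 to 1.14, RNS5 -0.032 to 0.016, RNS4 -0.053 to 0.062, COR15A -0.29 to 0.056, LHCB4.2 -0.996 to 0.51, LHCB4.1 -0.38 to 0.096, PSAN -0.61 to 0.45, RCA -0.29 to 0.20, PORB -0.59 to 0.52, GAMMA-VPE -0.13 to 0.46, ROF2 -0.57 to 0.22, HSP15.7 -0.26 to 0.062, ERDJ3B -0.056 to 0.75, BZIP60 -0.32 to 0.063, ZAT10 -0.60 to 0.17, CML37 -0.49 to 0.081, GSTU25 -0.63 to 0.33, UGT73B4 -0.25 to 0.18, XTH18 -1.05 to 0.11, EXPA4 -0.37 to 1.00, XTH19 -0.88 to 0.66, GH3.5 -0.11 to 0.71, ARR16 -0.21 to 0.31, ARR15 -0.0061 to 0.038, FAMA -0.088 to 0.28 and EXPA18 -0.35 to 0.067; in protoplasts WRKY6 -0.18 to 0.068, COR15A -0.64 to 0.067, PSAN -1.31 to 0.41, HSP22 -0.15 to 0.50, HSP17.6C -0.49 to 0.27, ERDJ3B -0.020 to 0.24, BZIP60 -0.22 to 0.18, ZAT10 -0.34 to 0.071, UGT73B5 -0.79 to 0.0021, UGT73B4 -0.61 to 0.18, GH3.5 -0.29 to 0.040, LBD16 -0.36 to 0.27 and GI -0.63 to 0.31. By scaling, RNS4 turned to -0.021 in seedlings under quantile normalization and -0.022 under median centring, RCA to 0.039 under quantile normalization, and median centring in protoplasts turned WRKY22 to -0.022, EIN3 to -0.033, CRT2 to -0.039, ERDJ3B to -0.060, BZIP28 to -0.12 and GC1 to -0.13. The turns by median centring in protoplasts follow from its shift of all probe sets by -0.17 and say nothing about single genes. For the others the cause was not tested. The alternatives of the ORE1 change were not run, as ORE1 has no listed probe set. The protoplast floor limits falls from dim genes.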

Other observations

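The families were grouped by gene symbol before any comparison was seen, and the genes singled out in this part outside the named rule were chosen after their values were seen, as was the test of the protoplast risers in seedlings.

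Some sugar transporters of the SWEET family rose in protoplasts. The family's median change there was 0, and 5 of 15 had a higher mean. Of 15 tested, 4 rose and none fell: SWEET15 by 9.15, SWEET7 by at least 5.21, SWEET2 by 1.60 ± 0.12 (SE) and SWEET17, which encodes a fructose transporter of the vacuolar membrane, by 1.26 ± 0.14. After quantile normalization 3 of the 7 then tested rose, and after median centring 4 of 7. The family's camera adjusted p was 0.00445 over 28 families, 0.0132 with the replicate number as a block, and 0.439 with an estimated correlation. Glycosyltransferases of the UGT family shifted the other way (median -0.19, camera adjusted p = 0.00486; adjusted p = 0.823 with an estimated correlation). The median of all probe sets was 0, with many exactly equal values, so camera can call a shift as small as that of the UGT family. Of 40, UGT71B6 (-1.48), UGT73C7 (-1.06) and UGT76C2 (-0.58) fell and UGT76D1 rose by 3.81, and after quantile normalization 2 members fell. Of the beta-glucosidase genes, BGLU40 and BGLU41 each rose by 5.36 while BGLU27 fell by 2.32 on the log2 scale. The tetraspanin gene TET10 rose by at least 5.11 and the endoglucanase gene GH9B17 by at least 4.17.

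The 69 genes grouped by symbol as chloroplast-encoded had a higher mean in 55 cases in protoplasts, by a median of 0.16 (camera adjusted p = 0.0334, and 0.823 with an estimated correlation). Some of the symbols used, such as those starting with atp, rps or rpl, can also stand for mitochondrion-encoded genes. None changed in the test. After centring each array on its median 34 were higher and 35 lower and the sign of their median turned, to -0.017. The median of all probe sets moved from 0 to -0.17. Centring moves all probe sets alike, so it leaves the gap between these genes and the rest as it was and cannot test it. In seedlings 23 of 69 were higher (median -0.08, camera adjusted p = 0.0269; adjusted p = 0.926 with an estimated correlation). The other family shifted in seedlings, grouped by the symbols LCR and PDF, had 8 of 9 members higher and none past the threshold (median 0.17, camera adjusted p = 0.0287; adjusted p = 0.926 with an estimated correlation and 0.186 with the replicate number as a block). Besides defensin-like genes such as PDF1.4 it holds the peptide deformylase genes PDF1A and PDF1B, so it is no single group by function.

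Probe sets that rose in protoplasts are shifted upward in seedlings. The brightness of these probe sets in seedlings is argued against: 0 of 10000 random lists matched on seedling level reached the observed median of 0.11, and the highest reached 0.06. A few strongly induced probe sets would not raise a median, and the share of the list with a higher mean with estradiol, 71.8% (95% interval 67.8 to 75.5, counting error only), restates the shift rather than testing it anew. A weak early form of the same response in seedlings may be a candidate explanation, found and tested on the same data. An effect of estradiol itself in seedlings cannot be examined, as no array measured estradiol without the inducible construct.

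For AT3G04000 the directions differed, with a value of 1.35 in seedlings (adjusted p = 0.213) and a fall by 0.95 in protoplasts (adjusted p = 0.0206), and the difference passed its test (adjusted p = 0.00412). BGLU27 had a difference of 2.29 (limma adjusted p = 0.0222) and FMO one of 1.78. Calls in this direction depended on the setting, with 27 in the main fit and 12 after quantile normalization. The probe set 267238_at, not listed with a gene, was higher by 3.79 ± 0.41 in seedlings (adjusted p = 0.213) and unchanged in value in protoplasts, where its arrays are equal within each pair.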
